A study of Homo sapiens with 8 samples.

How the data were processed

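Binding of HA-tagged RUNX1 was profiled by CUT&RUN in HEL cells, an erythroleukemia line with erythroid and megakaryocytic features. In CUT&RUN an antibody held on permeabilized cells directs a nuclease to its target, and the released DNA fragments are sequenced. Per the labels, 4 transduced lines were studied, with 2 biological replicates each, which makes 8 libraries. The lines carried wild-type RUNX1 (WT), RUNX1-4A, RUNX1-4D or an empty vector. By the usual naming of such mutants, 4A has serine or threonine residues replaced by alanine, which cannot be phosphorylated, and 4D has them replaced by aspartate, which mimics phosphorylation. Per the labels' protocols, each sample had 500000 cells, was selected in 2 µg/ml puromycin, permeabilized with 0.01% digitonin, incubated with an anti-HA antibody and amplified for 12 PCR cycles. The antibody reads only the tagged protein, so RUNX1 made by the cells themselves was not measured.

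Per the submitters' processing notes, the tools used upstream were cutadapt 3.4, Bowtie2 2.4.2, Picard 2.25.6, deepTools 3.5.1 and MACS2 2.2.7.1, on the human build hg38. The series design states that the empty vector line was the background for peak calling. Whether its replicates were pooled for that purpose, and how reads were filtered, is not given in the sources used here. The deposited files are 6 peak lists, 1 per library of WT, 4A and 4D, so peaks were called per library and the replicates can be compared. For each peak the authors' file gives a position, a summit, a score, a fold enrichment over background, which is a linear ratio, and the −log10 of a p-value and of a q-value. The lowest −log10 q of a list lay between 1.30 and 1.41, close to a q-value threshold of 0.05. These values are the authors' and were used only to describe, rank or filter peaks within a list. Read depth per library is unknown here, since a peak list holds no read totals. A region absent from a list was therefore not called at that library's depth, which does not show that it was unbound.

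Peaks on chromosomes 1 to 22, X and Y were used. No peaks of a list overlapped each other. The 6 lists were merged into a union of regions wherever peaks overlapped by at least 1 bp, and a region counted as called in a library when it held a peak of that library's list. A line's set is the regions called in both of its replicates. Coordinates are 1-based on hg38. Similarity of lists is the Jaccard index, the number of shared regions over the number in either list. For each pair of lines, regions called in both libraries of a line and in neither of the other were counted, beside the other ways of parting the same 4 libraries. The group log ratio is the natural log of the count called in exactly both libraries of the one line times that of the other line, over the product of the counts for the crossed pairs (replicate 1 of the one with replicate 2 of the other). A count of 0.5 was added to each. In simulations with the lengths of these lists and no group effect its mean was −0.0999 (4D against WT), 0.00705 (4A against WT) and −0.104 (4D against 4A). Its 95% interval came from 1000 bootstrap draws of genome blocks of 10 Mb, and covers regions, not cultures. The number log ratio was computed likewise, with pairs of the same replicate number in place of the pairs of a line. With 2 libraries against 2, an exact permutation test cannot go below p = 0.333, so single regions were not tested between lines. The number of peaks was compared over the 3 lines by an exact permutation test within replicate numbers on the log scale, chosen after seeing the data, which cannot go below p = 0.167.

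Genes came from a RefSeq table of the GRCh38.p14 assembly with gene starts and ends but no strand, exons or sequence. The design written beforehand asked for distances to transcription start sites. The distance to either end of a gene was used in their place, so a start site and a 3′ end cannot be told apart in any value given for gene ends. Summits were classed as within 1 kb of a protein-coding gene end, else within a gene body, else intergenic, with Wilson 95% intervals that cover counting error only. In place of the share of the genome in each class, the control was the same summits moved by 100 kb to either side. Sequence motifs at summits, and RUNX1 exons as opposed to the rest of RUNX1, were not analysed here.

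Altogether 9 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. They hold megakaryocyte and platelet genes (40), erythroid genes (42), blood transcription factors (36), RUNX1 targets known from the literature (30), myeloid genes (32), lymphoid genes (32), cell cycle genes (38), ribosomal protein genes (46) and genes of tissues outside the blood (35 matched of 36). The RUNX1 target list shares members with the others. A gene was called when a region of the line's set lay within 10 kb of either gene end. List genes were compared with all other protein-coding genes, of 20037, by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 27 tests of 9 lists in 3 lines. The same counts were set against 10000 random lists matched on gene length. To compare lines, genes called in exactly 1 of a pair of lines were sorted by which line held the call, and list genes were compared with other genes by two-sided Fisher's exact tests, again adjusted over 27. Genes are not replicates, so these p-values compare gene sets in the given libraries. A region within 10 kb of the ends of several genes counts for each, so genes that lie together are not independent. A direct comparison of megakaryocytic with erythroid genes was added after the list results had been seen.

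Regions and genes were named by a fixed rule. It took the 20 regions called in all 6 libraries with the highest mean percentile rank of −log10 q within their lists. For each direction of each pair of lines it took up to 8 regions by the lower of the ranks in the calling line. Each such region carries the name of the protein-coding gene with the nearest end within 100 kb, measured from the region's midpoint. The rule also took members of the megakaryocytic, erythroid, transcription factor and RUNX1 target lists with a region called in both libraries of a line and neither of another, up to 6 members per list with a region called in all 6 libraries, and RUNX1. Other genes are named as examples of list counts. Some regions and genes that the rule took are not reported here.

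Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data. All planted calls (100%) were recovered in the union. Without a group effect, the interval of the group log ratio lay above 0 in 0% (4D against WT), 10% (4A against WT) and 5% (4D against 4A) of 20 simulations and below 0 in 10, 0 and 5%, and with an effect on 5% of regions it lay above 0 in 100% for each pair. That effect gave mean log ratios of 2.99 (4D against WT), 2.83 (4A against WT) and 2.79 (4D against 4A). These exceed the ratios found in the data, and smaller effects were not simulated. For WT, 92.5% of 200 lists called at 45% against 20% were recovered over 20037 genes, and 6.5% passed at equal rates. For 4D against WT, the list difference was found for 90% of lists with 5 discordant genes and 98% with 10, at rates of 90% against 30%. These lists leaned to 4D and were judged before adjustment. Lists with fewer discordant genes, or leaning to WT, were not simulated. The alternatives tried were a −log10 q of at least 5, summits with 100 bp to either side in place of whole peaks, lists shortened to equal lengths, other distances to genes, blocks of 1 Mb, each replicate left out, the replicate number as a block and, chosen after seeing the data, leaving out chromosomes 10 and 14 and testing each library's list alone.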

Results

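The data are 6 lists of CUT&RUN peaks of HA-tagged RUNX1 in HEL cells, from 2 biological replicates each of the lines carrying WT RUNX1, RUNX1-4A and RUNX1-4D. The title of the series places the question in serine and threonine phosphorylation of RUNX1 and the choice between megakaryocytic and erythroid fate, and the comparisons ask where each form binds and whether the sites differ between forms. The replicate 1 lists held 6764 (WT), 6266 (4A) and 5358 (4D) peaks, and the replicate 2 lists 25911, 24251 and 21122. The means were 16337.5 ± 13539 for WT, 15258.5 ± 12717.3 for 4A and 13240.0 ± 11146.8 for 4D (SD, n = 2). Replicate 2 lists were 3.83 (WT), 3.87 (4A) and 3.94 (4D) times as long as replicate 1 lists. These SDs exceeded the differences between the means of the lines. Within each replicate number WT had most peaks and 4D fewest, with 4A at 0.926 (replicate 1) and 0.936 (replicate 2) times the WT number. Permuting the lines within each number gave an exact p = 0.167, the smallest this design allows. Peaks had median widths of 252 to 349 bp and covered 1.59 to 2.28 Mb in replicate 1 and 9.04 to 11.7 Mb in replicate 2.

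**Figure D1:**
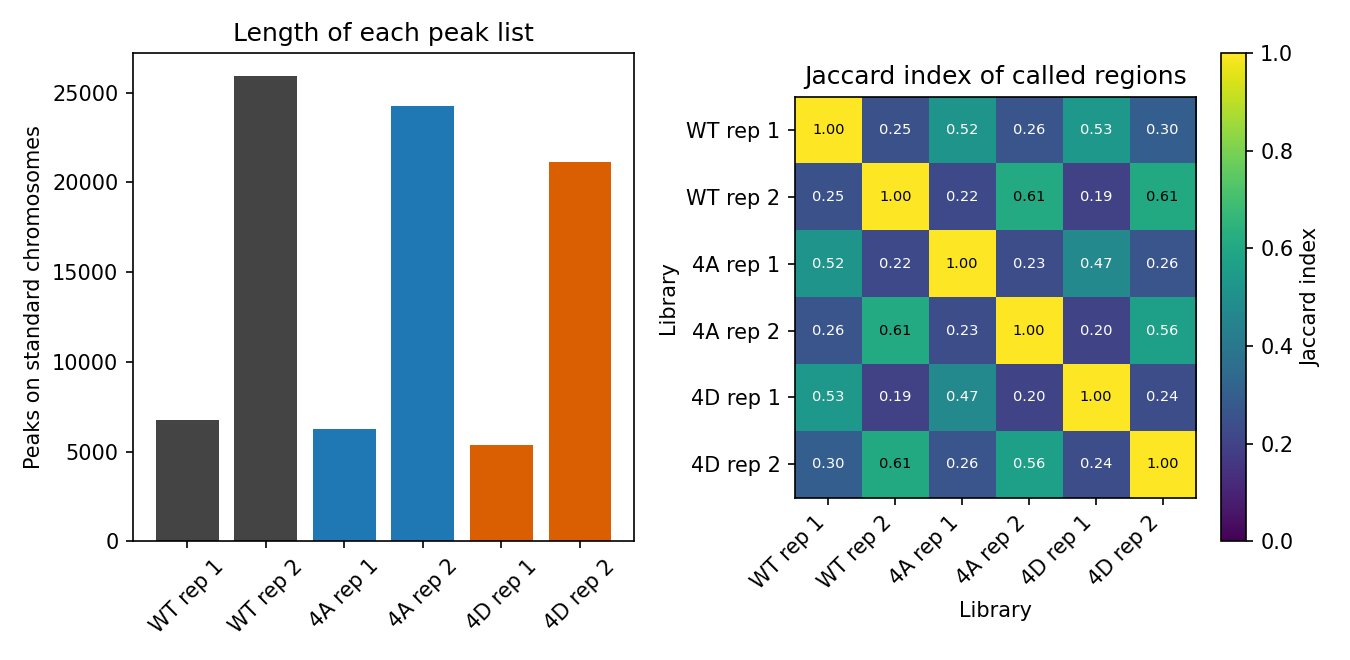
Left, the number of peaks in each of the 6 lists, with bars in grey for WT, blue for 4A and orange for 4D. Right, the Jaccard index of called regions for each pair of libraries, which lies at 0.47 to 0.61 for pairs with the same replicate number and at 0.23 to 0.25 for the replicates of a line, whose lists differ 3.83 to 3.94 times in length.

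All 3 forms of RUNX1 were found at a common set of 3295 regions called in all 6 libraries, out of 33478 regions in the union. Among the strongest were regions at LMO2, the adaptor protein of the TAL1 complex of blood stem and progenitor cells, at CDKN2D, an inhibitor of the cyclin-dependent kinases of G1, at IMPDH2, an enzyme of guanine nucleotide synthesis, and at SESN3, a stress-responsive regulator of growth signalling. The region with the highest mean rank lay 7.22 kb from NRROS, a myeloid protein that holds latent TGF-β (chromosome 3, 196631809 to 196633143). Its −log10 q was 205 and 347 in the WT replicates, 165 and 362 in 4A, and 121 and 343 in 4D. The LMO2 region (chromosome 11, 33885044 to 33886303) lay inside the gene, 6.40 kb from its nearer end, with fold enrichments over background between 29.6 and 37.0 in the 6 lists. The CDKN2D region (chromosome 19, 10565779 to 10567407) lay inside the gene 0.132 kb from an end, with fold enrichments between 18.3 and 37.1. Inside UBASH3B, a phosphatase that restrains tyrosine kinase signalling, 2 of the 20 named regions were found, starting at 122671108 and 122716538 on chromosome 11. The other named regions were nearest to LSM10, MTMR4, RSPH1, GRIP2, DRC10, RIC1, SPAG4, NFE2L1, WDCP, APLP2, TPCN1, ACAA1 and SH3GL2. Genes with most regions called in all 6 libraries, from 10 kb before to 10 kb after the gene, were GSE1 with 7 and RUNX1 and UBASH3B with 6 each. These genes span 507, 262 and 159 kb in that order, and the counts were not adjusted for gene length.

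RUNX1 was called at its own gene (chromosome 21, 34787801 to 35049302) in each line. Within 10 kb of the gene lay 25 regions, of which 6 were called in all libraries. The replicate 1 lists called 7 of them in WT and 8 each in 4A and 4D, and the replicate 2 lists called 21 in each line. The strongest by rank lay inside the gene 0.498 kb from its upper end (35047974 to 35049636), with −log10 q of 63.8 and 176 in WT, 58.5 and 172 in 4A, and 31.5 and 147 in 4D. Next to it, the region from 35045777 to 35047268 reached −log10 q of 262, 282 and 271 in the replicate 2 lists of WT, 4A and 4D. Reads from the transduced RUNX1 sequence were not separated from those of the gene itself, and exons were not analysed here.

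**Figure D2:**
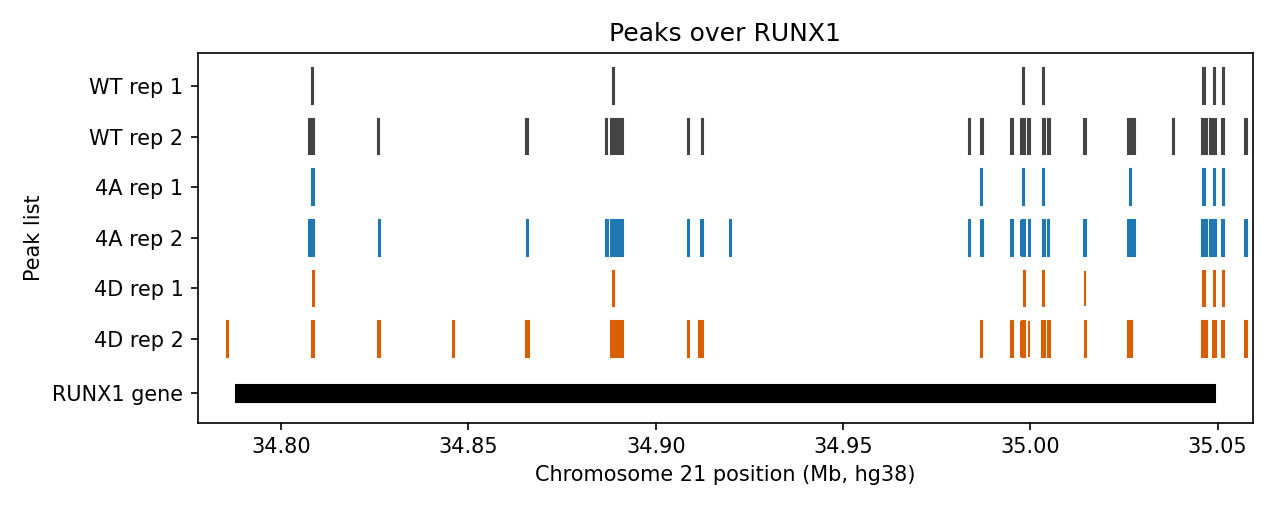
Peaks over RUNX1 and 10 kb to either side on chromosome 21 (position in Mb, hg38), with a line of boxes per list, outlined so that narrow peaks show, and the gene as a black bar. The replicate 2 lists call 21 of the 25 regions each and the replicate 1 lists 7 or 8, with a pair of strong regions near the upper end of the gene in every list.

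Genes of the megakaryocytic and platelet lineage were called near RUNX1 regions more often than other genes in each line. Of 40 such genes, 21 were called in WT, 18 in 4A and 17 in 4D, against 25.7%, 21.9% and 19.7% of other protein-coding genes. The odds ratios were 3.19, 2.93 and 3.04 (adjusted p = 0.00298, 0.00427 and 0.0033, two-sided Fisher's exact test). Regions in all 6 libraries lay at 17 of them, among them ITGA2B and ITGB3, the subunits of the platelet fibrinogen receptor, GP1BA, GP1BB and GP9 of the von Willebrand factor receptor, NFE2, a transcription factor of platelet formation, and the myosin genes MYH9 and MYH10. The MYH10 region (chromosome 17, 8628984 to 8631738) had fold enrichments between 25.9 and 45.4 in the 6 lists. No library had a region within 10 kb of either end of PF4, PPBP, P2RY12, CD226, CLEC1B, GNG11, MYL9 or PRKCQ. With only the longer replicate 2 list of a line, the odds ratios were 2.10 in WT, 2.11 in 4A and 2.27 in 4D, and the WT and 4A calls ended (adjusted exact p = 0.0592, 0.0502 and 0.0495). With only regions within 2 kb of a gene end the 4A call ended as well (odds ratio 2.27, adjusted exact p = 0.0971).

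Erythroid genes did not pass the same test in any line. Of 42, 9 were called in WT, 8 in 4A and 7 in 4D, with odds ratios of 0.819, 0.875 and 0.860 (adjusted exact p = 0.811, 0.885 and 0.885). Erythroid genes with regions in all 6 libraries included EPOR, the erythropoietin receptor, DMTN, a protein of the red cell skeleton, ERMAP and TRIM58. Compared directly, megakaryocytic genes were called more often than erythroid genes in WT (odds ratio 3.89, adjusted p = 0.0168), 4A (3.34, adjusted p = 0.0172) and 4D (3.52, adjusted p = 0.0172, Fisher's exact test). In the replicate 1 lists alone the counts were 21 against 9 genes in WT, 18 against 8 in 4A and 17 against 8 in 4D (adjusted exact p = 0.0335, 0.0515 and 0.0610). In WT and 4A these are the same counts as for both replicates, with the same unadjusted p. Only the adjustment differs, over 6 lists here and over 3 lines above. The result for both replicates is thus in effect that of replicate 1 in these lines. In the replicate 2 lists alone no line passed, with 29 against 27 genes in WT, 29 against 26 in 4A and 28 against 24 in 4D (adjusted exact p = 0.482, 0.424 and 0.387).

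Transcription factors of blood cells were called near regions more often than other genes in each line. Of 36, 20 were called in WT, 17 in 4A and 21 in 4D, with odds ratios of 3.60, 3.20 and 5.67 (adjusted exact p = 0.0021, 0.00316 and 1e-05). The list passed under each alternative, with odds ratios from 2.60 to 7.19 in WT, from 3.06 to 19.5 in 4A, the highest being without replicate 1, and from 3.04 to 7.47 in 4D, the lowest being with a −log10 q of at least 5. In all 6 libraries regions lay at 15 of them, including GATA1 and its cofactor ZFPM1, TAL1, LYL1 and LMO2 of the TAL1 complex, GFI1B, a repressor of erythroid and megakaryocytic cells, STAT5A, and the RUNX family genes RUNX1 and RUNX3 with their partner CBFB. The STAT5A region (chromosome 17, 42311745 to 42313334) lay 0.596 kb outside the gene, with −log10 q of 258, 335 and 209 in the replicate 2 lists of WT, 4A and 4D. RUNX1 targets known from the literature were called at 17 (WT), 15 (4A) and 14 (4D) of 30 genes, with odds ratios of 3.75, 3.56 and 3.59 (adjusted exact p = 0.00298, 0.00316 and 0.00316). Examples are CSF2 and IL3, which encode growth factors of myeloid cells, CCND3, a cyclin, and ANKRD26. A region between CSF2 and IL3 (chromosome 5, 132068881 to 132071384) counts for both genes. The enrichment of RUNX1 targets was not past the threshold in any line when only regions within 2 kb of a gene end counted (odds ratios 2.00, 1.86 and 2.49, adjusted exact p = 0.188, 0.326 and 0.109). Without replicate 1 it ended in WT and 4D (adjusted exact p = 0.0865 and 0.105), by the nearest gene end in 4A and 4D (0.101 and 0.117), and with a −log10 q of at least 5 in WT (0.0604).

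Cell cycle genes were called at 19 of 38 in WT (odds ratio 2.90, adjusted exact p = 0.00388), 13 in 4A (1.88, adjusted p = 0.139) and 14 in 4D (2.42, adjusted p = 0.0319). Among them were CCND2 and CCND3, E2F1, CDK2, CDC6, CDC20, MCM2 and MCM3. The WT call ended with a −log10 q of at least 5, with all lists at one length and by the nearest gene end (odds ratios 2.19, 1.79 and 2.18, adjusted exact p = 0.0614, 0.297 and 0.0954). The 4D call ended under the same settings (1.91, 1.42 and 2.07, adjusted exact p = 0.198, 0.732 and 0.117), with whole gene bodies (0.104), without replicate 1 (0.431) and against random lists matched on gene length (adjusted permutation p = 0.0823). In 4A the list passed without replicate 1 and within 2 kb of a gene end (adjusted exact p = 0.0453 and 0.0380). Myeloid genes (9, 8 and 8 of 32), lymphoid genes (6, 8 and 5 of 32) and ribosomal protein genes (12, 11 and 6 of 46) did not pass the test in any line (adjusted exact p from 0.594 to 1.00). The myeloid genes CSF3R, CD33, ELANE, CST7 and TYROBP and the lymphoid genes CD3E, NKG7 and PRF1 nevertheless had regions in all 6 libraries. Genes of tissues outside the blood were called less often than other genes in WT (3 of 35, odds ratio 0.311, adjusted exact p = 0.0426). The values were 0.382 in 4A (3 of 35, adjusted exact p = 0.124) and 0.303 in 4D (2 of 35, adjusted p = 0.0693). The WT call ended against random lists matched on gene length (adjusted permutation p = 0.0618) and under 5 other settings (adjusted exact p from 0.0534 to 0.199). Without replicate 1 the 4A list passed (odds ratio 0.254, adjusted exact p = 0.00105), and the 4D list passed with each other distance to genes (odds ratios 0.0926 to 0.250, adjusted exact p from 0.0343 to 0.0482).

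**Figure D3:**
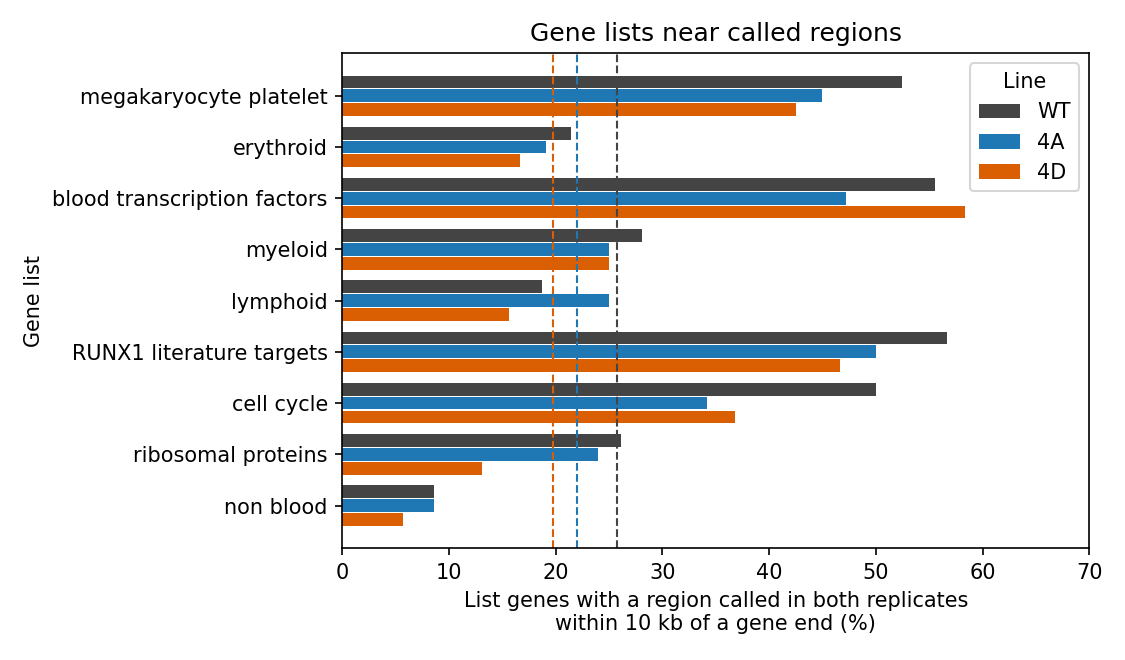
Percent of the genes of each of 9 lists with a region called in both replicates of a line within 10 kb of a gene end, as bars in grey (WT), blue (4A) and orange (4D). Dashed lines give the percent of all protein-coding genes in the same line (25.7, 22.0 and 19.7). The bars of megakaryocytic genes, transcription factors, RUNX1 targets, cell cycle genes and myeloid genes exceed them in every line. The myeloid list passed its test in no line, and the cell cycle list did not pass in 4A.

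Peaks of every form were concentrated at the ends of genes. Summits within 1 kb of a protein-coding gene end made up 34.4 ± 8.94% of peaks in WT, 32.3 ± 3.74% in 4A and 33.1 ± 4.99% in 4D (SD, n = 2). For summits moved by 100 kb the means were 5.29, 5.11 and 5.16%. The lines differed from each other by less than their replicates. The single libraries ranged from 28.1% (WT replicate 2, 95% Wilson interval 27.5 to 28.6) to 40.7% (WT replicate 1, 39.5 to 41.9).

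For 4D against WT, the comparison asks how 4D, by its name a phosphomimetic form, differs in its sites from the wild type. Regions called in both WT replicates and in neither 4D replicate numbered 158, and in the opposite direction 38, beside 4045 regions called in all 4 libraries. Found with WT and not 4D were regions near EPB42, a protein of the red cell membrane, and near CEBPE, a transcription factor of granulocytes. The EPB42 region (chromosome 15, 43230697 to 43231064) lay 5.14 kb outside the gene, with −log10 q of 8.55 and 4.88 in WT and 11.4 and 4.36 in 4A. The CEBPE region (chromosome 14, 23112765 to 23113029) lay 4.41 kb outside the gene and had −log10 q of 2.70 and 10.4 in WT. Other regions within 10 kb were called at EPB42 in 4D replicate 2 and at CEBPE in 4D replicate 1. With a −log10 q of at least 5 or with all lists at one length neither region was found with WT and not 4D, nor was that near CEBPE with equal lengths within each number. By rank, the leading region of this direction lay inside EPM2A, which encodes a glycogen phosphatase (chromosome 6, 145470940 to 145471117), with −log10 q of 19.5 and 23.2 in WT and no call in 4A or 4D. Others included those inside PTPRG, a receptor tyrosine phosphatase, DYNLL1, a dynein light chain, and STYXL1, and those 6.96 kb from SNAP47, 58.8 kb from CCDC68 and 81.1 kb from MTSS1. Of these, the PTPRG, DYNLL1, STYXL1 and CCDC68 regions were also called in 4A replicate 2 and the SNAP47 region in 4A replicate 1. Found with 4D and not WT were regions inside SLC1A3, a glutamate transporter (chromosome 5, 36611649 to 36611880, −log10 q of 10.6 and 19.3 in 4D), 40.7 kb from SC5D, an enzyme of cholesterol synthesis, and inside SGIP1. The SLC1A3 and SC5D regions were also called in 4A replicate 1 (−log10 q of 14.7 and 4.12). Another lay over FBXL13, 48.0 kb from LRRC17, and was called in both 4A replicates as well, and another over IL16, 39.7 kb from STARD5. With all lists at one length, 2 of the 8 regions named by rank for WT, among them that in STYXL1, and 0 of the 8 for 4D were still found with the 1 line and not the other.

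Most of these regions ranked low in their lists. Their median lower percentile rank of −log10 q was 15.02 (WT not 4D) and 13.5 (4D not WT), against 65.8 and 57.3 for regions shared by the 4 libraries, and the highest was 75.1 (EPM2A, WT not 4D). The 4D lists were 0.792 (replicate 1) and 0.815 (replicate 2) times as long as the WT lists. With lists shortened to equal lengths within each replicate number the counts were 55 (WT not 4D) and 71 (4D not WT), so the larger count changed sides. The group log ratio was 0.858 (95% interval 0.316 to 1.39), above 0, and 0.527 (0.0537 to 1.06) at equal lengths within each number, but its interval held 0 with summit windows (0.231, −0.191 to 0.617) and with all lists at one length (0.317, −0.0481 to 0.709). No gene list passed the test of a difference between 4D and WT. Of the megakaryocytic genes 0 were in the 4D set but not the WT set and 4 the other way round (DIAPH1, GP6, RAB27B and TUBB1; adjusted p = 1.00, Fisher's exact test), and of the erythroid genes 1 (EPB41) and 3 (CA1, EPB42 and XPO7; adjusted p = 1.00). Genes outside the megakaryocytic list split 438 to 1637, so 4 genes could not pass even with all on the WT side. The test therefore cannot decide whether megakaryocytic genes were lost from the 4D set. All 4, and the 3 erythroid genes, were called in 4D replicate 2 and were missing only from the shorter replicate 1 list. Likewise EPB41 was called in WT replicate 2. Between the replicate 2 lists, 2 megakaryocytic genes were called in 4D only and 3 in WT only.

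For 4A against WT, the comparison asks the same of 4A, by its name the form with residues replaced by alanine. Regions called in both WT and neither 4A replicate numbered 90, and in the opposite direction 69, beside 4270 shared by the 4 libraries. Found with WT and not 4A were regions 37.7 kb from PLXNA1, a semaphorin receptor (chromosome 3, 127074929 to 127075275), 66.5 kb from FZD7, a Wnt receptor, 2.29 kb from IQSEC3 and 40.1 kb from SMIM21, and inside CEP63, a centrosome protein, GTF2IRD1 and EPM2A. The PLXNA1 region had −log10 q of 29.8 and 24.7 in WT and 11.3 and 28.2 in 4D. DCHS1 was the nearest gene to another, at 12.03 kb. The IQSEC3, CEP63 and SMIM21 regions were also called in both 4D replicates, and those of FZD7, GTF2IRD1 and DCHS1 in 4D replicate 2. Found with 4A and not WT were regions inside FCHO1, a protein of clathrin endocytosis (chromosome 19, 17775134 to 17775458, −log10 q of 11.6 and 34.0 in 4A), and inside RCAN1, a calcineurin inhibitor (chromosome 21, 34534522 to 34534926), and 37.2 kb from ETS2, a transcription factor of the ETS family, and 42.1 kb from CKAP4. The region over FBXL13 was also found with 4A and not WT. With all lists at one length, 2 of the 8 regions named by rank for WT (near IQSEC3 and DCHS1) and 1 of the 8 for 4A (FCHO1) were still found so. On chromosome 14 lay 7 of the 69 regions found with 4A and 0 of the 90 found with WT.

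The group log ratio was −0.172 (95% interval −0.641 to 0.267), so no parting of the lists by line was detected. The crossed pairs gave 125 and 59 regions. With lists of equal lengths within each replicate number the WT count fell to 54 and the 4A count was 75. No gene list passed the test of a difference, with 0 megakaryocytic genes in the 4A set but not the WT set and 3 the other way round (DIAPH1, GP6 and RAB27B), and 1 (EPB41) and 2 (CA1 and XPO7) erythroid genes (adjusted p = 1.00 each, Fisher's exact test). Genes outside the megakaryocytic list split 652 to 1402, so 3 genes all on the WT side could not pass. Whether megakaryocytic genes were lost from the 4A set is not decided by this test. The 3 megakaryocytic genes, CA1 and XPO7 were called in 4A replicate 2 and were missing only from replicate 1, and EPB41 was called in WT replicate 2. Between the replicate 2 lists, 2 megakaryocytic genes were called in 4A only and 2 in WT only.

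For 4D against 4A, the comparison sets the form that by its name has aspartate at the replaced residues against the form that has alanine. Regions called in both 4A and neither 4D replicate numbered 224, and in the opposite direction 105, beside 3566 shared by the 4 libraries. Found with 4A and not 4D were regions inside IFNAR2, a subunit of the type I interferon receptor (chromosome 21, 33259936 to 33260301, −log10 q of 19.2 and 38.6 in 4A), 17.2 kb from ZFPM2, a cofactor of GATA factors (chromosome 8, 105821465 to 105822040, 14.3 and 62.1 in 4A), inside FOCAD and KIAA1549, and 3.22 kb from CCDC15 and 20.6 kb from PCNX1. Of the list members, EPB42 and EGR1, an immediate early transcription factor (chromosome 5, 138476363 to 138476763), also had a region nearby called with 4A and not 4D, but not with a −log10 q of at least 5 or all lists at one length, and that of EGR1 not at equal lengths within each number. Found with 4D and not 4A were regions inside NRG2, a ligand of ERBB receptors (chromosome 5, 139877696 to 139878298, −log10 q of 21.3 and 49.7 in 4D), inside NFATC4, a transcription factor driven by calcineurin, inside CDC42EP3, near PLXNA1 and IQSEC3, 16.8 kb from MAS1 and 21.7 kb from MVB12B. Each of these regions named by rank, in both directions, was also called in WT replicate 2. Those of NRG2, CDC42EP3, PLXNA1, IQSEC3 and CCDC15 were called in WT replicate 1 as well. With all lists at one length, 5 of the 8 regions named by rank for 4A, among them those of IFNAR2, ZFPM2 and KIAA1549, and 4 of the 8 for 4D (NRG2, PLXNA1, IQSEC3 and MVB12B) were still found so.

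The group log ratio was 1.17 (95% interval 0.804 to 1.57), and its interval lay above 0 under each alternative tried. It was 0.770 (0.440 to 1.13) with summit windows and 0.658 (0.374 to 0.957) with all lists at one length. The number log ratio of the same libraries was larger, at 2.84 (2.05 to 3.41) in the main setting. With equal lengths within each replicate number, 140 regions were found with 4D and not 4A and 133 with 4A and not 4D, so the excess on the side of 4A did not hold. Of the transcription factors, 5 were in the 4D set but not the 4A set (FLI1, FOSL1, HHEX, LDB1 and MECOM) and 1 the other way round (EGR1), with p = 0.0359 before and 0.970 after adjustment (Fisher's exact test). In the replicate 2 lists those counts were 0 and 5. Over the 3 pairs of lines, 0 of 27 list differences passed the adjusted threshold and 1 had an unadjusted p under 0.05.

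Shared regions were counted for each pair of lists. The Jaccard index was 0.508 ± 0.0330 among the replicate 1 lists and 0.595 ± 0.0260 among the replicate 2 lists (SD, 3 pairs each), and 0.240 ± 0.00691 between the replicates of a line (SD, 3 pairs). For pairs that shared neither line nor number it was 0.241 ± 0.0403 (SD, 6 pairs). Unequal lengths cap the index between a replicate 1 and a replicate 2 list. With all lists at one length the means were 0.442 within lines and 0.581 within numbers. The shorter list of a line was largely contained in the longer one. Of the replicate 1 regions, 97.0% (WT), 92.7% (4A) and 95.1% (4D) were called in replicate 2 as well, which gave sets of 6382, 5681 and 4962 regions. In the 3 replicate 2 libraries and no other, 7478 regions were called. Of the shorter list, 69.7 to 84.8% was called in the longer one for lists with the same number, and 90.8 to 96.2% for pairs that shared neither.

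In a single library the peaks were unevenly spread over chromosomes. Chromosome 14 held 292 of 6266 peaks (4.66%) of 4A replicate 1, 1.65 times the share in WT and 4D replicate 1 (2.83%, adjusted p = 4.42e-08 over 144 tests, Fisher's exact test). Chromosome 10 held 2.44% of its peaks against 3.61% (0.676 times, adjusted exact p = 0.00106). The only other of the 144 tests to pass was chromosome 14 in WT replicate 1 (0.750 times, adjusted exact p = 0.0327), which is compared with 4A replicate 1 among others. In 4A replicate 2 the share of chromosome 14 was 1.02 times that of the other lines. Of the 224 regions found with 4A and not 4D, 21 lay on chromosome 14, among them the one near PCNX1.

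**Figure D4:**
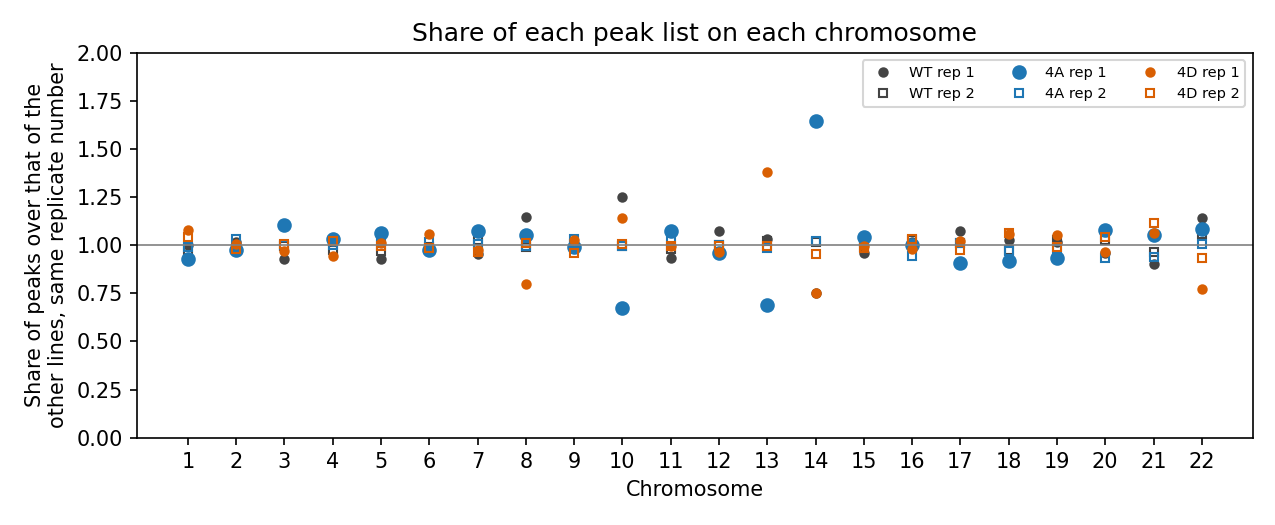
Share of each list's peaks on each autosome (horizontal axis), divided by the share in the other lines with the same replicate number (vertical axis, ratio), with filled circles for replicate 1, open squares for replicate 2, and grey, blue and orange for WT, 4A and 4D. 4A replicate 1 lies at 1.65 on chromosome 14 and at 0.676 on chromosome 10.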

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

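The signals in this part lie in data outside the comparisons, and none of them was tested. Peaks on the mitochondrial genome, which is outside the chromosomes compared, covered 14.02 kb in WT replicate 1, 15.4 kb in 4A replicate 1 and 14.6 kb in 4D replicate 1. In replicate 2 they covered 2.05 kb in WT, 0.518 kb in 4A and 10.9 kb in 4D. The highest −log10 q of a mitochondrial peak was 874, 1366 and 1179 in the replicate 1 lists of WT, 4A and 4D, above that of any peak on the chromosomes compared (230, 167 and 145). In the replicate 2 lists it was 51.9, 15.2 and 245, below the highest on those chromosomes (440, 502 and 450). On unplaced contigs, the WT lists held 1 (replicate 1) and 9 (replicate 2) peaks, the 4A lists 1 and 2, and the 4D lists 2 and 4.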

How the results depend on the processing

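Leaving out chromosomes 10 and 14 and testing each library's list alone were chosen after the results were seen. No value past its test changed direction. The larger count of a pair changed sides with equal lengths within each number, to 71 (4D not WT) against 55, 75 (4A not WT) against 54 and 140 (4D not 4A) against 133, and for 4D and 4A with all lists at one length (214 against 210). It also changed sides without replicate 1 of the line with fewer regions, to 3076 (4D not WT) against 192, 4994 (4A not WT) against 133 and 4442 (4D not 4A) against 251, and without replicate 2 of the other line (903 against 286, 1390 against 195 and 1369 against 523). For regions called in a line and not the other, the order of values below is 4D not WT, WT not 4D, 4A not WT, WT not 4A, 4D not 4A and 4A not 4D, with 38, 158, 69, 90, 105 and 224 in the main setting. A −log10 q of at least 5 gave 15 (4D not WT), 42 (4A not WT) and 68 (4D not 4A). Summit windows gave 68 (4D not WT), 117 (4A not WT) and 143 (WT not 4A). All lists at one length gave 116 (4D not WT), 120 (4A not WT), 141 (WT not 4A) and 214 (4D not 4A). Equal lengths within each number gave 71 (4D not WT), 55 (WT not 4D), 54 (WT not 4A) and 133 (4A not 4D). Leaving out each replicate gave ranges of 52 to 3076, 192 to 7999, 90 to 4994, 133 to 6682, 132 to 4442 and 251 to 7674, since a single list then stands for its line. The highest values came without replicate 1 of the line that holds the call.

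The labels do not say what libraries with the same number share, so the replicate block stands here. A batch shared by a number stays open, with a Jaccard index of 0.581 within numbers and 0.442 within lines when all lists had one length. Within number 1 the replicate block gave 1109, 2470, 1784, 2233, 1582 and 2494 regions, and within number 2 it gave 3129, 8098, 5074, 6850, 4576 and 7769. As the common odds ratio over both numbers, the replicate block moved no list difference past the threshold (lowest adjusted exact p = 0.677, with 1 of 27 unadjusted p under 0.05).

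The group log ratio of 4D against WT was 0.231 with summit windows and 0.317 with all lists at one length, where its interval held 0, and the cause was not tested. For 4D against 4A it ranged from 0.658 to 1.25, above 0 throughout, and for 4A against WT from −0.268 to 0.186, with 0 inside throughout. Leaving out a replicate gives this ratio no value. The Jaccard index within lines was 0.223 with summit windows and 0.442 with all lists at one length. Regions called in both replicates numbered 3342 (WT), 3233 (4A) and 3171 (4D) at that length, and ranged from 6576 to 25560, 6127 to 23784 and 5215 to 20591 without a replicate. Within 5 kb of a gene end lay 47.6% (WT), 45.7% (4A) and 46.1% (4D) of summits, by the wider distance.

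In WT, 5 lists passed the threshold in the main setting, against 2 with a −log10 q of at least 5, 3 with all lists at one length, 3 by the nearest gene end within 100 kb, and 3 to 5 without a replicate. In 4D it was 4, and 2 to 4 without a replicate, the 2 being without replicate 1. The odds ratio of the megakaryocytic list without a replicate was 2.10 to 3.09 in WT and 2.11 to 2.81 in 4A, and within 2 kb of a gene end it was 2.27 in 4A (adjusted exact p = 0.0971). Across all settings its adjusted p reached 0.0592 in WT, 0.0971 in 4A and 0.0495 in 4D. The transcription factor list passed under each setting in each line. Erythroid genes passed in none, with odds ratios from 0.406 to 1.51. The cause of these changes was not tested.

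All 20 named regions of the 6 libraries were kept under 4 other ways of calling. They had been chosen for the highest ranks of −log10 q, so the settings that cut lists by this value could not remove them. Of the 48 named for a pair of lines, 47 were kept with a −log10 q of at least 5, 48 with summit windows, 48 with equal lengths within each number and 14 with all lists at one length. These too were chosen for high ranks in the calling line, the lowest being 28.2, and a shortened list gains no call. Equal lengths within each number, which cut only low ranks, thus could not remove them, and the −log10 q threshold could remove few. Summit windows keep every summit, so the calling line could not lose its calls. The alternatives foreseen for RUNX and other motifs (window widths, patterns, controls, thresholds and list lengths) were not run, for lack of a genome sequence. Regions called in a line and not the other had median lower percentile ranks from 13.5 to 21.6, and the highest of each direction lay between 62.2 and 88.7. Read depth is unknown here, so its effect on these counts was not tested.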

Other observations

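The lists of this part were written before their test but after the main results had been seen. Chosen after the result was seen were the test of different sites in replicate 1, all 3 tests of chromosome 14, the counts near other kinds of genes and leaving out chromosomes 10 and 14. Genes of cytokine and JAK-STAT signalling were called near regions at 20 of 30 in WT, 19 in 4A and 14 in 4D (odds ratios 5.66, 6.05 and 3.59, adjusted p = 1.15e-05, 5.1e-06 and 0.00154 over 4 lists, Fisher's exact test). Regions in all 6 libraries lay at 14 of them, including the transcription factors STAT3, STAT5A and STAT6, the feedback inhibitors CISH, SOCS2 and SOCS3, the receptor subunits IL4R, IL6R and IL6ST, and SH2B3. Genes of adhesion and the cytoskeleton were called at 19, 17 and 14 of 30 (odds ratios 4.91, 4.62 and 3.59, adjusted exact p = 3.12e-05, 7.52e-05 and 0.00154), among them TLN1, VCL, FERMT3 and ILK, which link integrins to actin. Chromatin regulators were called at 17, 13 and 10 of 30 (odds ratios 3.75, 2.75 and 2.09, adjusted exact p = 0.000588, 0.0104 and 0.0675), with EP300, KDM1A and SMARCA4 in all 6 libraries. Genes of apoptosis were called at 14, 12 and 10 of 30 (odds ratios 2.54, 2.405 and 2.09, adjusted exact p = 0.0121, 0.0252 and 0.0675), with BAX, BBC3 and CASP9 in all 6. All 4 lists thus passed in WT and 4A, and in 4D the chromatin and apoptosis lists did not. Differences between lines were not tested for these lists.

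Near genes for transfer RNAs, regions called in both replicates lay within 1 kb of 20 of 443 genes in WT, 19 in 4A and 11 in 4D, against 0.451% of them for regions moved by 100 kb. These shares were 10.0, 9.5 and 5.5 times those of the moved regions, and for microRNA genes they were 2.75, 2.75 and 2.67 times. For transfer RNA genes a moved share of 0.451% of 443 rests on very few genes, so the ratios and their differences between lines are imprecise. Pseudogenes lay near regions less often than near moved ones (0.503, 0.519 and 0.508 times). Transfer RNA genes lie in clusters, so they are not independent, and no test was made.

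The replicate 2 lists were nearly 4 times as long as the replicate 1 lists in each line. Different sites bound in replicate 1 are argued against, since at most 7.28% of a replicate 1 list lay outside the replicate 2 list of its line. Lower detection power in replicate 1 may account for the gap. Among replicate 2 regions, those also called in replicate 1 had the higher −log10 q with an area under the curve of at least 0.844 in each line, as this explanation predicts. Any longer list that adds weaker calls to the same strong ones gives such an area. It therefore cannot tell lower power in replicate 1 from extra weak calls in replicate 2. If power was lower, whether read depth or signal over background was the reason stays open, since read depth is unknown here. The median fold enrichment of called peaks was higher in replicate 1 (7.54 in WT, 6.92 in 4A, 6.94 in 4D) than in replicate 2 (6.19, 5.08 and 5.68). Only called peaks enter these medians, so they cannot decide between the 2. With all lists at one length, the share of summits within 1 kb of a gene end was still higher in replicate 1 than in replicate 2. It was 40.4 against 30.6% in WT, 34.6 against 31.9% in 4A and 36.6 against 28.3% in 4D. List length alone thus does not account for every difference between the replicates.

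Chromosome 14 carried an excess of peaks in 4A replicate 1. Binding by the 4A form itself is argued against by 4A replicate 2, where the ratio to the other lines was 1.02. A background library shared by replicate 1 is argued against by WT and 4D, where the share of chromosome 14 in replicate 1 was at most 1.01 times that in replicate 2. A candidate explanation is extra copies of chromosome 14 in that culture, since all 8 bins of 10 Mb with at least 20 peaks had a ratio above 1, from 1.35 to 2.24. Copy number was not measured here, so this stays a hypothesis found and tested on the same peaks.

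The regions of 4D and 4A parted by line with a group log ratio of 1.17. The uneven chromosomes are argued against as the whole source, since the log ratio without chromosomes 10 and 14 was 1.18 (95% interval 0.798 to 1.60). Unequal list lengths are argued against as the whole source, with 1.23 (0.865 to 1.63) at equal lengths within each replicate number, but a part stays open, since the ratio was 0.658 (0.374 to 0.957) with all lists at one length. A difference of the line other than the RUNX1 form, such as the amount of tagged protein, cannot be told apart from the form itself, since the labels name 1 transduced line per form. An effect of the changed residues on the choice of sites is therefore open, and may be followed up with independent lines.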
